A study of Rattus norvegicus with 8 samples.

How the data were processed

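Whole kidneys of 8 rats at 4 weeks of age were measured, 4 from HSRA-S animals with a congenital solitary kidney and 4 from HSRA-C animals with both kidneys. Per the labels' protocols, RNA was isolated with TRIzol and a PureLink kit, its quality was checked on an Experion system, and biotin-labelled cRNA was hybridised to Rat Gene 1.1 ST arrays on the Affymetrix GeneAtlas platform, with 1 array per sample. The labels call the samples biological replicates, and the series' design text calls them independent. Sex, litter and collection time of the animals are not given in the sources used here.

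The deposited values are RMA summaries per the submitters' processing notes, whose software and version are not given in the sources used here. RMA corrects background, sets the probe intensity distributions of the arrays equal and sums up the probes of a transcript, so small array-wide differences are already removed. The values deposited by the authors are intensities on a linear scale, from 2.12 to 9259 with array medians of 30.8 to 32.3, whereas RMA itself gives log2 values. The design fixed beforehand assumed log2 values, and the log2 of the deposited intensity was therefore taken before any test. RMA values of low intensity are compressed, so differences of dim genes tend to be understated.

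Of 29214 probe sets, 18644 were paired with exactly 1 gene symbol, 962 with several and 9608 with none in the platform annotation used here. Of the first kind, 18460 matched a gene of the RefSeq table of assembly GRCr8 by gene ID, and 0 symbols changed. Genes were named only from probe sets with 1 symbol. Where a gene had several probe sets, which held for 879 of 17245 genes, the one with the highest mean over all 8 arrays was used. The dimmest 20% of genes by mean over all arrays were left out, which removed 3449 genes below a log2 mean of 3.63 and left 13796. All 8 value columns of the table were used. No genome build is named with the values, so no coordinates are given.

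HSRA-S was compared with HSRA-C by limma (lmFit and eBayes without trend) on log2 values of all 8 arrays, with group as the only term and Benjamini-Hochberg adjustment over the 13796 genes at a threshold of 0.05. Differences are HSRA-S minus HSRA-C, and standard errors (SE) are on the log2 scale throughout. Adjusted p-values of genes come from this fit, and intervals are 95% intervals of the fit. A descriptive count of genes at an unadjusted p under 0.05 and at least 1.5-fold was kept beside it. Of 27 gene lists with 773 entries fixed before the data were examined, 26 had at least 5 tested members. The list of sex-linked genes had fewer and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry and with an exact two-sided permutation of the list mean per array, whose smallest possible p is 0.0286. P-values of lists were adjusted over the 26 lists. Camera compares a list with all other genes, while fry and the permutation test the list alone. Counts of list genes are given over all genes and after Benjamini-Hochberg adjustment over the list alone. Enrichment of genes at an unadjusted p under 0.01 on a chromosome was tested with Fisher's exact test, two-sided and adjusted over 21 chromosome groups. The outcome for single arrays was examined by principal components of the tested genes.

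Genes were named by a rule fixed before the data were examined. It takes up to 12 genes per direction past the adjusted threshold without overlap between groups, filled up with genes of smallest p without overlap where fewer passed. It adds up to 4 members of smallest p in each list described, and 2 genes whatever their values, of which Kit is given and the other is not reported here. Unnamed gene models and olfactory and vomeronasal receptors were skipped in the first part. Slc7a7, Ccr2, Cd14, Havcr1, Krt19, Aqp4, Slc14a2, Ldha, Slc28a2, Clstn2, Nrip3, Tmem72 and the clock genes other than Per3, Clock, Usp2 and Wee1 fall outside this rule and were chosen after their values were seen.

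The steps were tested on simulated data made from the spread and means of the 13796 genes, with 200 genes changed in each of 20 runs. At an adjusted p under 0.05, 83.6% of genes changed 1.5-fold were called, 97.3% of those changed 2-fold and 99.4% of those changed 3-fold, and 4.81% of the calls were unchanged genes. A list of 30 genes moved by 0.2 was called in 20 of 20 runs, and 0.4% of unmoved lists were called. The simulated genes varied independently, which the genes of real samples do not. The share of changed genes called also depends on how many genes change, because the adjustment is less strict where many do. In the real comparison 0 genes passed, so these shares do not give its power for a gene changed 1.5-fold.

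Alternatives fixed before the data were examined were no filter on dim genes, leaving out the dimmest 50%, all probe sets named or not, the mean over a gene's probe sets, an intensity trend with robust variance, array weights, a further quantile normalization, centring on array medians, the replicate number as a block, leaving out each array in turn, an adjusted threshold of 0.1, an unmoderated test per gene, and the other list tests. After seeing the data 2 were added: leaving out HSRA-C replicates 3 and 4, and the difference between the means of the proximal tubule and collecting duct lists as a covariate. Camera with an estimated correlation was then also run in both and without each array in turn. Whether the shared replicate numbers pair the samples was checked by the correlation of deviations from the group means. A planned covariate for sex was not run, because Xist and Y-linked genes are not analysed here. Computations used R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.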

Results

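Whole kidneys of the HSRA rat were compared at 4 weeks of age. HSRA is a rat model derived from a heterogeneous stock in which some animals are born with a single kidney. The HSRA-S group consisted of animals with a congenital solitary kidney, and the HSRA-C group of animals with a kidney pair, which served as the control. Each group held 4 independent samples, and each sample was measured on its own Affymetrix Rat Gene 1.1 ST array. Median probe set intensities ran from 30.8 to 32.3 across the 8 arrays, and the arrays correlated at 0.987 to 0.995 with one another on the log2 scale. The number of arrays limits the precision of every value below. The comparison addresses how gene expression in a kidney that developed alone differs from that in a kidney of a 2-kidney animal of the same strain and age.

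Differences between the solitary and the control kidneys were small in size, and no single gene passed the test. The clearest gene was Hoxb5 (probe set 10737722), a homeobox transcription factor. Its log2 level was 6.29 ± 0.051 in HSRA-S and 6.82 ± 0.059 in HSRA-C (SD, n = 4 each), a 1.45-fold lower level in the solitary kidney. The log2 difference was -0.53 with a 95% interval from -0.66 to -0.40, and the adjusted p was 0.0558. Eya1, a transcriptional coactivator needed for the early kidney to form, was 1.34-fold lower in HSRA-S (log2 difference -0.43, SE 0.087). Porcn, the acyltransferase that lipid-modifies Wnt proteins, was 1.31-fold lower (SE 0.064 on the log2 scale). Aqp6, an aquaporin of intercalated cells, was 1.34-fold lower at a log2 level of 9.54 ± 0.14 against 9.96 ± 0.12 (SD, n = 4 each). On the higher side, Gdf15, a stress-induced cytokine of the TGF-beta superfamily, was 1.49-fold higher in HSRA-S (log2 difference 0.58, SE 0.11). F3, the tissue factor that starts coagulation, was 1.45-fold higher (SE 0.10 on the log2 scale), and Cidea, a lipid droplet protein, was 1.47-fold higher (SE 0.092).

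Of 13796 genes tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1663 genes, of which 1016 were higher and 647 lower in HSRA-S, against 689.8 expected with no effect. Both criteria of p under 0.05 and at least 1.5-fold were met by 62 genes, 35 higher and 27 lower. The values of 868 genes, or 6.29% of those tested, did not overlap between the groups, where chance gives 2.86% on average. Genes vary together, so a single split of the samples can lie far from the chance figures of 689.8 genes and 2.86%. Another split into 4 and 4 gave 1677 genes at an unadjusted p under 0.05. The 868 genes were not set against other splits. Leaving out HSRA-C replicates 3 and 4, which stood apart from the other samples, reduced the 62 genes to 19 and the 1663 genes to 669. Leaving out a single sample moved the 62 genes between 21 (without HSRA-C replicate 4) and 132 (without HSRA-C replicate 1 or replicate 2), and the 1663 genes down to 1010 without HSRA-C replicate 3 and 1017 without HSRA-C replicate 4. The unmoderated test per gene gave 0 genes after adjustment as well, with 1438 at an unadjusted p under 0.05.

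Because no gene passed, the 12 genes of smallest p in each direction whose values did not overlap between groups are described, and none of these 24 is a call. The lower genes besides Hoxb5, Eya1, Porcn and Aqp6 were Pamr1, Car11, Lratd1, Kiaa0825, Pcdhb16l, Spmip4, Ralgds and Dusp14. Their log2 differences lay between -0.57 for Spmip4 and -0.28 for Dusp14, a dual-specificity phosphatase. Car11, a carbonic anhydrase-related protein, was at -0.45, Pcdhb16l, a clustered protocadherin, at -0.39, and Ralgds, an exchange factor for Ral GTPases, at -0.32. The higher genes besides Gdf15, F3 and Cidea were Nabp1, Dgkg, Uap1l1, Tas2r139, Tsku, RT1-CE5, Ube2l6, Nasp and Shq1. Nabp1, a single-stranded DNA binding protein, had the widest difference at 0.66, while Shq1, an assembly factor of small nucleolar ribonucleoproteins, stood at 0.29. Dgkg, a diacylglycerol kinase, was at 0.52, Tas2r139, a bitter taste receptor, at 0.49, and RT1-CE5, a class I histocompatibility gene, at 0.37. Tas2r139 and RT1-CE5 were dim, with the filter on dim genes at a log2 mean of 3.63. Tas2r139 was at log2 4.12 in HSRA-S and 3.62 in HSRA-C, and RT1-CE5 at 4.48 and 4.10. Nasp, a histone chaperone, was at 0.35 and Ube2l6, the conjugating enzyme of ISG15, at 0.36. Apart from Hoxb5, the adjusted p of these genes lay between 0.249 and 0.331.

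**Figure D1:**
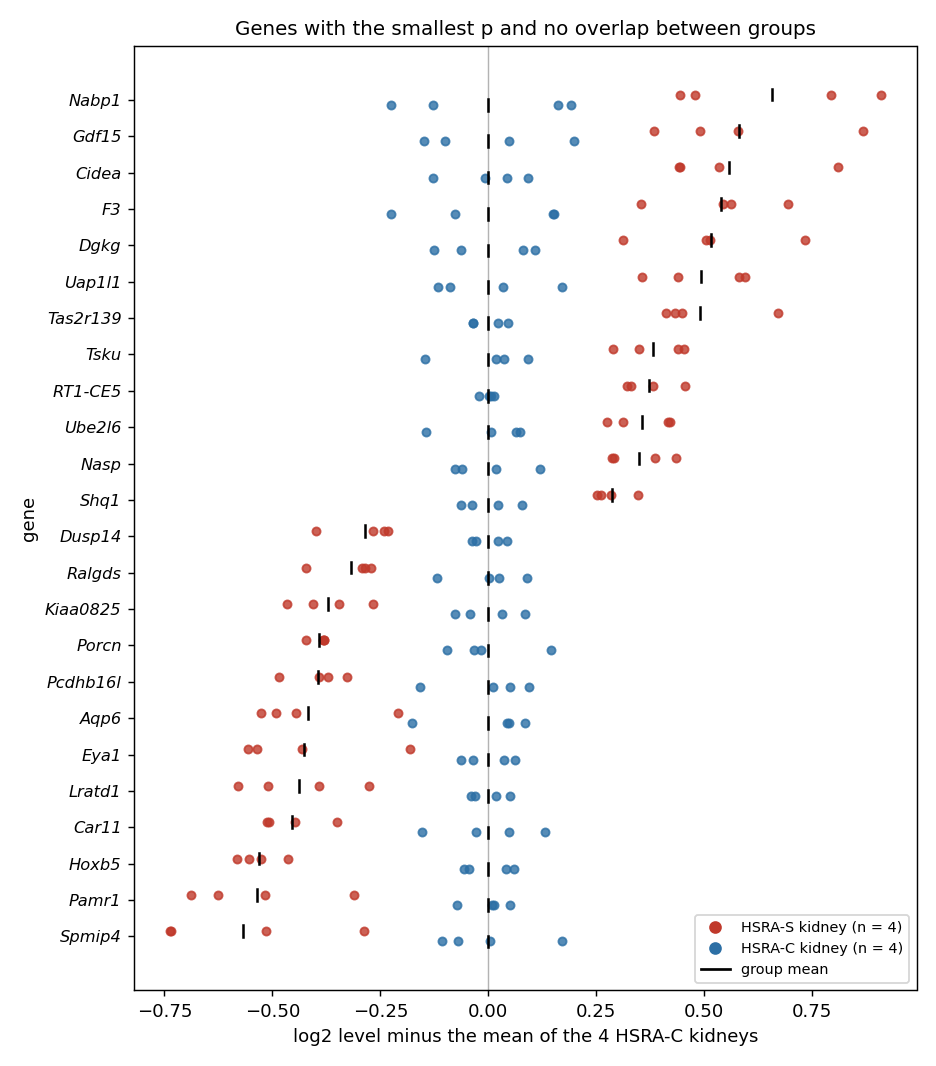
Log2 level of each of the 24 genes of smallest p without overlap between groups, in each kidney, after subtracting the mean of the 4 HSRA-C kidneys. Points are single kidneys (red HSRA-S, blue HSRA-C, n = 4 each) and black bars are group means. Group mean differences range from -0.57 for Spmip4 to 0.66 for Nabp1, and none of the 24 genes passed at an adjusted p under 0.05.

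Kit, the receptor tyrosine kinase for stem cell factor, had been singled out before the data were examined. It was 1.30-fold lower in the solitary kidney (log2 5.72 ± 0.16 against 6.10 ± 0.076, SD, n = 4 each; difference -0.37, SE 0.084). Its groups did not overlap, and its adjusted p was 0.331 over all genes and 0.0209 over the kidney development list alone.

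The 2 control samples HSRA-C replicates 3 and 4 differed from the other 6 in markers of the medulla. They scored 16.7 and 19.5 on the first principal component, which held 35.9% of the variance, while the other samples scored between -12.8 and -1.20. Slc14a2, the urea transporter of the inner medullary collecting duct, was at log2 8.86 and 9.0 in these samples and between 4.44 and 7.22 in the others. Aqp4, a water channel of medullary collecting duct cells, was at 7.31 and 7.57 against 5.22 to 6.79. The mean of the proximal tubule list minus that of the collecting duct list was 1.55 and 1.51 in these samples. It was 2.59 in HSRA-S replicate 4 and between 1.96 and 2.11 in the remaining samples. Each gene list below that passed is therefore given also without HSRA-C replicates 3 and 4. The proximal tubule to collecting duct difference was also used as a covariate, and the value with it is given where the covariate ended a call or moved a shift by over 1.5 times, or where leaving out the 2 samples ended the call. Both alternatives were chosen after seeing the data.

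**Figure D2:**
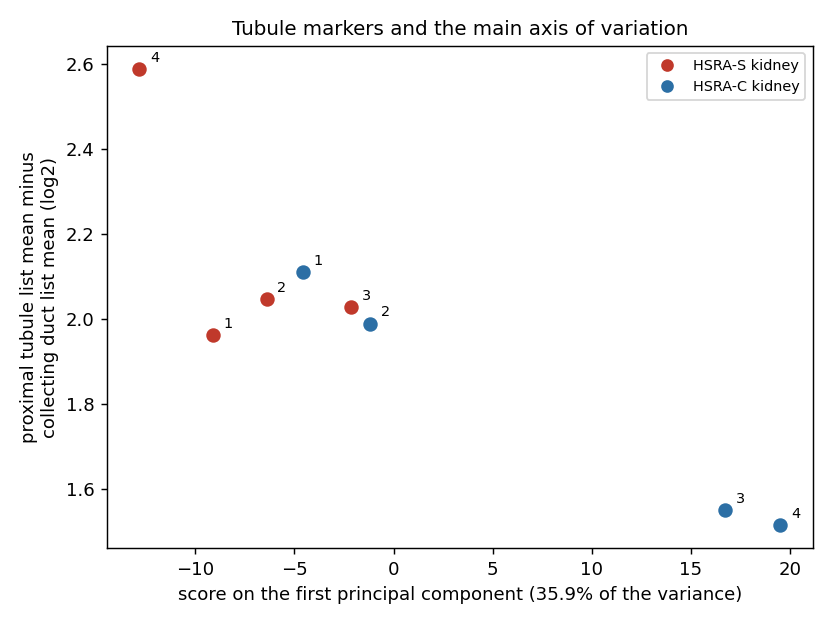
Score of each of the 8 kidneys on the first principal component (x axis, 35.9% of the variance) against the mean log2 level of the proximal tubule list minus that of the collecting duct list (y axis). Points are single kidneys with their replicate number. HSRA-C replicates 3 and 4 lie at 16.7 and 19.5 on the x axis with differences of 1.55 and 1.51, and HSRA-S replicate 4 has the highest difference at 2.59.

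Gene lists fixed before the data were examined showed a broader pattern. Genes of cell division, mitochondrial metabolism, leukocytes and the proximal tubule were on average higher in the solitary kidney. Those of vessels, matrix, kidney development, glomerulus and collecting duct were on average lower. With limma's camera and its preset correlation of 0.01, 13 of 26 lists passed at an adjusted p under 0.05, of which 7 were higher and 6 lower. None of the 26 passed with an estimated correlation (smallest adjusted p = 0.389) or with fry (smallest adjusted p = 0.167). None passed with an exact permutation of the list means over the samples either (smallest adjusted p = 0.279). That permutation could hardly pass any list, since its smallest possible p is 0.0286 and many lists would have to reach it together. The list calls given below for other samples or with a covariate use the preset correlation too, and with an estimated correlation 0 lists passed in any of them (smallest adjusted p = 0.0998). Where a member loses its call over the list alone without HSRA-C replicates 3 and 4, 6 arrays enter the test in place of 8, and its difference there is given. Lists share some genes, so their shifts are not independent of each other.

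Cell cycle genes had the largest mean difference. Of 40 tested members, 38 were higher in HSRA-S, by 0.31 on the log2 scale on average (camera adjusted p = 5.4e-07; adjusted p = 0.420 with an estimated correlation). Ribonucleotide reductase subunit Rrm2 was 1.57-fold higher, cyclin Ccnb1 1.63-fold and topoisomerase Top2a 1.61-fold, with SEs of 0.20, 0.22 and 0.23 on the log2 scale, and the mitotic kinesin Kif11 was 1.31-fold higher. The number of members past the threshold was 0 over all genes and 0 adjusted over the list alone. The list mean took 2 levels that crossed the groups: it was 5.90 to 5.93 in HSRA-S replicates 1 to 3 and 5.87 in HSRA-C replicate 2, but 5.49 in HSRA-S replicate 4 and 5.32, 5.45 and 5.34 in the remaining HSRA-C samples. Without HSRA-C replicates 3 and 4 the mean difference was 0.22.

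Leukocyte genes were higher in HSRA-S by 0.24 on average, with 24 of 28 members on that side (camera adjusted p = 7.4e-06; adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone 6 members passed, against 0 over all genes. Of these 6, the complement component C1qc (log2 difference 0.47, SE 0.11), the class II histocompatibility genes RT1-Ba (0.37, SE 0.095) and RT1-Da (0.45, SE 0.14), the coreceptor Cd4 (0.50, SE 0.14) and the chemokine receptor Ccr2 (0.43, SE 0.13) rose, and the endotoxin coreceptor Cd14 fell (-0.21, SE 0.063). A second probe set of Cd4 had the opposite sign. The mean difference without HSRA-C replicates 3 and 4 was 0.19, and 0 members then passed adjusted over the list alone, with Cd4 at 0.45, RT1-Ba at 0.31, C1qc at 0.32, RT1-Da at 0.29, Ccr2 at 0.24 and Cd14 at -0.24.

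Mitochondrial lists were higher as well. All 40 tested genes of oxidative phosphorylation were higher in HSRA-S, by 0.11 on average (camera adjusted p = 1.2e-06; adjusted p = 0.411 with an estimated correlation). The succinate dehydrogenase subunit Sdhb was 1.19-fold higher (SE 0.058 on the log2 scale) and the complex I subunit Ndufa1 1.28-fold (SE 0.098). No member of that list passed over all genes or adjusted over the list alone, 0 in both. Fatty acid oxidation genes were higher by 0.17, in 27 of 33 members (camera adjusted p = 6.6e-06; adjusted p = 0.409 with an estimated correlation). Here 1 member, the peroxisomal protein Pex11a (1.22-fold, SE 0.060), rose adjusted over the list alone and 0 over all genes, while the isomerase Eci1 was 1.58-fold higher (SE 0.20) without passing. The mean differences without HSRA-C replicates 3 and 4 were 0.062 for oxidative phosphorylation and 0.12 for fatty acid oxidation, with 0 members of either list past adjustment over the list alone and Pex11a at 0.22 against 0.29. With the covariate the call of fatty acid oxidation ended (0.088, camera adjusted p = 0.0904), and oxidative phosphorylation was at 0.070.

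The list of glutathione metabolism and NRF2 targets was higher by 0.12 (25 of 31 members; camera adjusted p = 0.00290; adjusted p = 0.420 with an estimated correlation). Thioredoxin reductase Txnrd1 was 1.25-fold higher (SE 0.077) and the glutathione peroxidase Gpx2 1.49-fold (SE 0.16), and 0 members passed over all genes or adjusted over the list alone. Its shift was 0.070 without HSRA-C replicates 3 and 4, where the camera adjusted p was 0.234 and the call ended, as it did without HSRA-S replicate 3 (0.080, camera adjusted p = 0.0765). With the covariate it was 0.14 and the list passed (camera adjusted p = 0.0318). Chaperone and ER stress genes were higher by 0.078 (22 of 30 members; camera adjusted p = 0.0226; adjusted p = 0.389 with an estimated correlation), and by 0.066 without those samples. That call ended without HSRA-S replicate 3 (0.072, camera adjusted p = 0.0892) and without HSRA-C replicate 3 (0.065, camera adjusted p = 0.0945). The member of that list with the smallest p, Phgdh, is a serine synthesis enzyme and was 1.29-fold higher, and the mitochondrial chaperonin Hspd1 was 1.21-fold higher, with 0 members past either adjustment.

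Along the nephron, proximal tubule genes were higher in HSRA-S by 0.17 on average, with 23 of 30 members on that side (camera adjusted p = 0.00295; adjusted p = 0.570 with an estimated correlation). Adjusted over the list alone 5 genes rose, against 0 over all genes: the glucose transporter Slc2a2 (log2 difference 0.75, SE 0.19), the phosphate transporter Slc34a3 (0.58, SE 0.15) and the amino acid transporters Slc7a7 (0.69, SE 0.20), Slc6a19 (0.48, SE 0.13) and Slc7a8 (0.44, SE 0.10). This list moved with the medullary markers of the control samples: without HSRA-C replicates 3 and 4 its mean difference was 0.044, its camera adjusted p was 0.882 and 0 members passed adjusted over the list alone, with Slc2a2 at 0.56, Slc34a3 at 0.31, Slc7a7 at 0.38, Slc6a19 at 0.33 and Slc7a8 at 0.29. The list forms part of the covariate and was not tested with it. The call also ended without HSRA-S replicate 4 (0.12, camera adjusted p = 0.122). Collecting duct genes were lower by 0.20 (20 of 24 members; camera adjusted p = 0.000372; adjusted p = 0.409 with an estimated correlation), by 0.063 without those samples and by 0.10 without HSRA-S replicate 4. The water channel Aqp2 was 1.30-fold lower (SE 0.15) and the intercalated cell factor Foxi1 1.21-fold lower (SE 0.082), with 0 members past either adjustment. Thick ascending limb and distal tubule genes did not pass (mean difference 0.055, camera adjusted p = 0.665), although the calcium binding protein Calb1 was 1.35-fold higher (SE 0.13) and the calcium channel Trpv5 1.43-fold (SE 0.17).

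Kidney development genes were lower in HSRA-S by 0.12 on average, in 25 of 34 members (camera adjusted p = 6.9e-05; adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone, Eya1, Kit and the basement membrane protein Fras1 (-0.34, SE 0.082) fell, 3 genes against 0 over all genes. The guidance receptor Robo2 was 1.18-fold lower (SE 0.070). Without HSRA-C replicates 3 and 4 the mean difference was -0.040, with Eya1 at -0.43, Kit at -0.33 and Fras1 at -0.23, and 0 members passed adjusted over the list alone. It was -0.046 with the covariate. Podocyte and glomerulus genes were lower by 0.11 (21 of 25 members; camera adjusted p = 0.000119; adjusted p = 0.389 with an estimated correlation). The transcription factor Tcf21 was 1.36-fold lower (SE 0.12), the integrin ligand Npnt 1.18-fold (SE 0.080), and 0 members passed over all genes or adjusted over the list alone. That list's difference was -0.058 without the 2 samples and -0.047 with the covariate.

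Stromal and vascular lists pointed to the same side. Extracellular matrix genes were lower by 0.16 in 25 of 30 members (camera adjusted p = 7.6e-06; adjusted p = 0.420 with an estimated correlation). The proteoglycan Dcn fell adjusted over the list alone (log2 11.2 ± 0.20 against 11.6 ± 0.081, SD, n = 4 each; difference -0.43), 1 gene against 0 over all genes. The proteoglycan Vcan was 1.97-fold lower with an SE of 0.33, and its difference of -0.98 became -0.31 without HSRA-C replicates 3 and 4. Endothelial genes were lower by 0.12 in 17 of 20 members (camera adjusted p = 6.6e-06; adjusted p = 0.389 with an estimated correlation), with the junction protein Cdh5 1.16-fold lower (SE 0.061), and 0 members passed either adjustment. The mean differences without those samples were -0.068 for matrix, with 0 members past adjustment over the list alone and Dcn at -0.38, and -0.042 for endothelium. With the covariate the call of the matrix list ended (-0.042, camera adjusted p = 0.186), and endothelium was at -0.042. Smooth muscle and pericyte genes did not pass (mean difference -0.068, camera adjusted p = 0.111), but did without HSRA-S replicate 3 (-0.10, camera adjusted p = 0.0233). Adjusted over that list alone the pericyte regulator Rgs5 fell (-0.44, SE 0.12) and the smooth muscle actin Actg2 rose (0.27, SE 0.073), 2 genes against 0 over all genes. Neither passed without HSRA-C replicates 3 and 4, with Actg2 at 0.25 and Rgs5 at -0.25.

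The angiotensin and aldosterone list was lower by 0.058, in 10 of 16 members (camera adjusted p = 0.0233; adjusted p = 0.389 with an estimated correlation), and by 0.061 without HSRA-C replicates 3 and 4. Its members went both ways: adjusted over the list alone, angiotensin-converting enzyme Ace fell (-0.58, SE 0.16) and the adrenoceptor Adra1a rose (0.75, SE 0.18), 2 genes against 0 over all genes. Neither passed without HSRA-C replicates 3 and 4, with Ace at -0.54 and Adra1a at 0.45. The call ended with the covariate (-0.013, camera adjusted p = 0.116), without HSRA-S replicate 4 (-0.020, camera adjusted p = 0.122) and without HSRA-C replicate 1 (-0.055, camera adjusted p = 0.0585). The peptidase Mme was 1.20-fold lower (SE 0.086) and the angiotensin receptor Agtr1b 1.24-fold lower (SE 0.12).

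The remaining 13 lists did not pass, and their camera adjusted p lay between 0.0669 and 0.791. Growth factor and mTOR genes differed by -0.035 on average, with cyclin Ccnd1 1.19-fold higher (SE 0.086) and the growth factor Hgf 1.36-fold lower (SE 0.17). Tubular injury genes differed by 0.019, with a median of -0.026; of these, Gdf15 rose adjusted over the list alone, 1 gene against 0 over all genes, and the injury marker Havcr1 had a difference of 0.30 with an SE of 0.38. Without HSRA-C replicates 3 and 4 the tubular injury list was higher by 0.12 and passed (camera adjusted p = 0.0433), where over the list alone the keratin Krt19 passed (0.70, adjusted p = 0.00321) and Gdf15 did not (0.46, adjusted p = 0.124), and the lists of adipose tissue (0.098, camera adjusted p = 0.0433) and of hypoxia and glycolysis (0.068, camera adjusted p = 0.0465) passed as well. With an estimated correlation these 3 calls were lost (adjusted p = 0.590 for tubular injury and adipose tissue and 0.675 for hypoxia and glycolysis). Hypoxia and glycolysis genes differed by 0.052, cholesterol synthesis genes by 0.071, interferon response genes by 0.032 and clock genes by 0.032. Immediate early genes, which respond to handling of tissue, differed by 0.0016 on average while their median was -0.020 and the test's direction was lower. Without HSRA-S replicate 1 the immediate early list passed as lower (-0.081, camera adjusted p = 0.0324), as did growth factor and mTOR genes (-0.060, camera adjusted p = 0.0373). Cholesterol synthesis genes passed as higher without HSRA-C replicate 2 (0.14, camera adjusted p = 0.00340) or HSRA-S replicate 4 (0.12, camera adjusted p = 0.0359), and blood cell genes without HSRA-C replicate 1 (0.27, camera adjusted p = 0.00520). Adipose genes passed without any 1 of 5 samples (0.10 to 0.13). Without HSRA-C replicates 3 and 4 the mean difference changed sign for cholesterol synthesis (-0.048, camera adjusted p = 0.0736), interferon response (-0.027) and growth factor and mTOR genes (0.012). It also changed sign for blood cell (-0.0078), adrenal (0.027) and urothelial genes (0.11). The test's direction there stayed lower for growth factor and mTOR genes. It turned to lower for clock genes (mean difference 0.015) and to higher for immediate early genes (0.10). With the covariate urothelial genes turned as well and passed as higher (0.22, camera adjusted p = 0.0318), and hypoxia and glycolysis genes passed (0.090, camera adjusted p = 0.0459). The mean difference of growth factor and mTOR (0.040), clock (-0.0016) and adrenal genes (0.0073) changed sign with the covariate. Single samples changed the sign of the mean difference of tubular injury (-0.027 without HSRA-C replicate 1, -0.0040 without HSRA-C replicate 2), immediate early (-0.029 and -0.034 there), urothelial (0.038 without HSRA-S replicate 4) and adrenal genes (0.0022 without HSRA-C replicate 3). Among markers of neighbouring tissues, adipose genes differed by 0.10 (camera adjusted p = 0.0669), with Cidea and the triglyceride synthesis enzyme Dgat2 higher adjusted over the list alone, 2 genes against 0 over all genes; without HSRA-C replicates 3 and 4 Cidea passed over the list alone and Dgat2 did not (0.24, adjusted p = 0.131). Blood cell genes differed by 0.14 (camera adjusted p = 0.340), adrenal genes by -0.019 (median 0.018) and urothelial genes by -0.098 (median 0.0037).

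**Figure D3:**
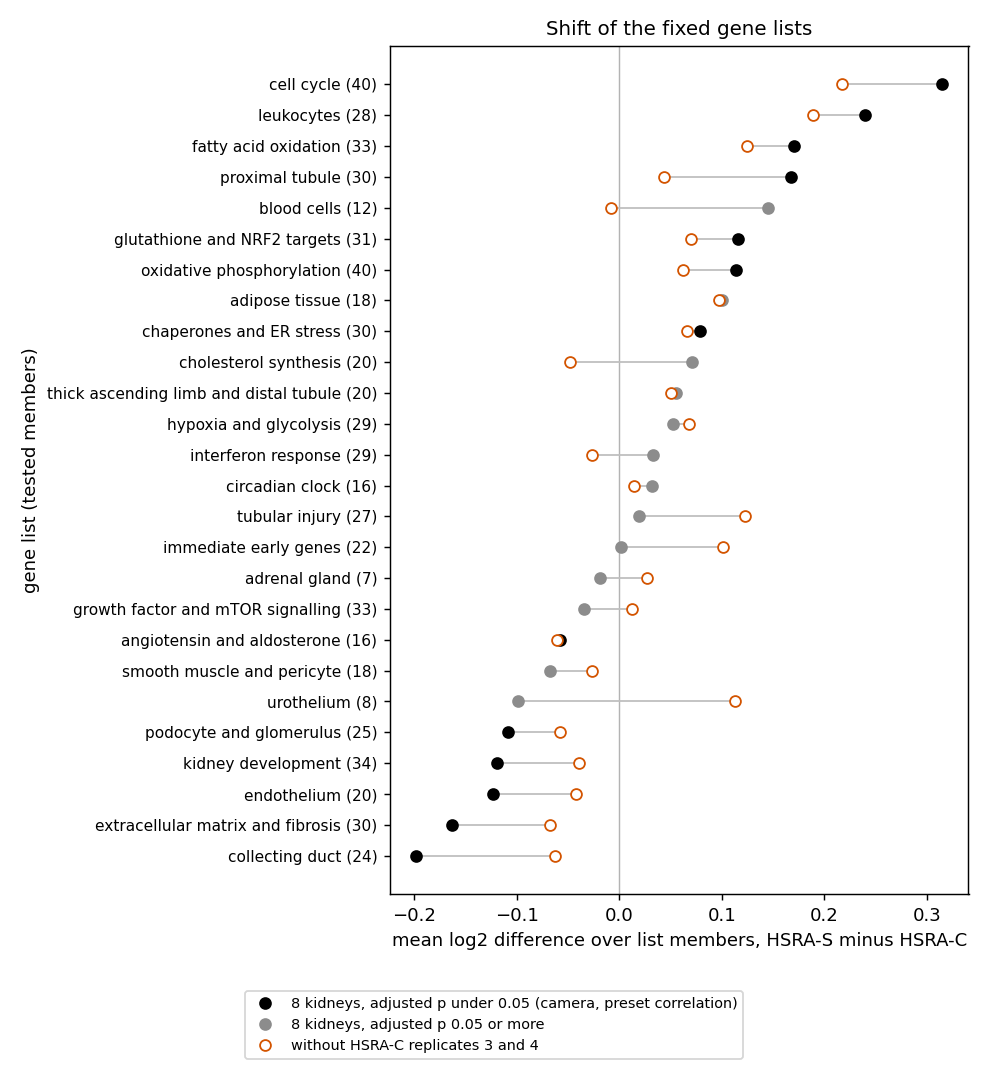
Mean log2 difference (HSRA-S minus HSRA-C) over the tested members of each of 26 gene lists, with the number of tested members in parentheses. Filled points are all 8 kidneys, black where the camera adjusted p with a preset correlation was under 0.05 and grey otherwise, and open points leave out HSRA-C replicates 3 and 4. The cell cycle list moves from 0.31 to 0.22 and the collecting duct list from -0.20 to -0.063.

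Genes of small p were not concentrated on any chromosome. Of 13682 genes placed on a chromosome, 404 had an unadjusted p under 0.01, and Fisher's exact test found 0 of 21 chromosome groups with more or fewer of them than the rest (smallest adjusted p = 0.588).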

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

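The tests of array-wide intensity, of the proximal tubule list, of the 24 genes without HSRA-C replicates 3 and 4 and of genes picked in other splits, and of other splits for the number of genes past the adjusted threshold were chosen only after the result was seen, as were the alternatives without HSRA-C replicates 3 and 4, with or without an estimated correlation, and with the proximal tubule to collecting duct difference as a covariate.

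Among 200 values per group of named genes and gene lists, 17 held a sample far from the other 3 of its group by Dixon's criterion, where chance gives about 10. HSRA-S replicate 4 was low for Top2a (6.62, others from 7.31), C1qc (5.06, others from 5.35), Cd4 (6.12, others from 6.61), the cell cycle list mean (5.49, others from 5.90) and the interferon response list mean (5.30, others from 5.50). HSRA-S replicate 3 was high for Slc4a1, an anion exchanger (8.75, others up to 8.23), and low for Ralgds (5.82), the carnitine acetyltransferase Crat (9.11) and the carnitine carrier Slc25a20 (7.07). HSRA-S replicate 2 was high for Tas2r139 (4.30) and low for Porcn (5.69, with the other 3 all at 5.73 or 5.74). HSRA-S replicate 1 was high for the podocyte and glomerulus list mean (7.21) and the immediate early list mean (6.10, others up to 5.78). In the control group, HSRA-C replicate 1 was low for Aqp6 (9.78), HSRA-C replicate 2 was high for Ccnb1 (5.65, others up to 4.87) and the chaperone Hspa4 (8.99), and HSRA-C replicate 3 was low for the chaperone and ER stress list mean (8.09).

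Other splits of the 8 samples into 4 and 4 bear on how far chance can be excluded. For the 1663 genes at an unadjusted p under 0.05, 2 of 35 splits gave as many genes, the real one included, with 1677 in the other, so chance is not excluded. For the 62 genes that were also at least 1.5-fold apart, 3 of 35 splits gave as many, with up to 99, so chance is not excluded there either. The real split gave 0 genes past the adjusted threshold, which all 35 splits reach, and the highest other gave 78. That split set HSRA-S replicates 1 to 3 and HSRA-C replicate 2 against the other 4 samples and called 20 of 40 cell cycle genes, 3 of 28 leukocyte genes and 2 of 29 interferon response genes, which points to a structure of the samples other than the study's groups. For chromosomes the real split gave 0 groups, which 35 of 35 splits reach, with 1 in the highest other.

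HSRA-C replicates 3 and 4 stood apart on the first principal component with high levels of Slc14a2 and other medullary genes. After RMA no array-wide intensity difference was seen. The median log2 level of these samples exceeded that of the other 6 by 0.027 on average and lay inside their range. RMA had already set the array distributions equal, so this test cannot exclude a difference that arose before that step. More inner medulla or papilla in the RNA is a candidate explanation that stays open: 6 of 6 measured inner medulla genes not examined before were higher in these samples, but by a median of 0.15, less than the 0.2 set beforehand. For lower glucocorticoid signalling, a median fall of over 0.2 in its target genes was set beforehand as the mark. A positive median was set as speaking against it. The median over 9 measured target genes was 0.051, on the side against it. These genes went both ways, from -0.51 to 0.16 with 4 lower, and the median is small beside that spread, so the explanation is not excluded. The labels place both samples in the control group and give no further difference between these animals, so lower glucocorticoid signalling was the biological explanation tested and others were not.

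The shift of 13 of the 26 gene lists may come in part from HSRA-C replicates 3 and 4. Without them 11 of the 13 lists kept their direction and a camera adjusted p under 0.05, but that p assumes a correlation of 0.01, while the correlations estimated over all 8 samples reached 0.53, and with an estimated correlation 0 lists passed without the 2 samples (smallest adjusted p = 0.590), so these samples are not excluded as the cause. The median ratio of the mean shifts was 0.55: the shift fell to 0.26 of its size for the proximal tubule list, whose call ended and whose shift is consistent with these samples as a source, and to 0.32 for collecting duct, 0.33 for kidney development and 0.34 for endothelium. As many lists were called in 6 of 35 splits, with up to 15 lists, so chance is not excluded for their number, and a list call with the preset correlation is weak evidence here. The difference between solitary and control kidneys stays among the open explanations.

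The 24 genes of smallest p without overlap between groups were set against the medullary contrast. With the proximal tubule to collecting duct difference as a covariate, the median ratio of their log2 differences to those without it was 0.94, with single genes from 0.74 to 1.11. Without HSRA-C replicates 3 and 4 the median ratio was 0.94 as well, from 0.72 to 1.13. Genes picked for smallest p without overlap in other splits of the samples gave median ratios of 0.79 to 1.01 with the covariate (34 splits) and 0.83 to 1.01 without the 2 samples (14 splits that hold both in 1 group), so the way the genes were picked fixes such ratios and they exclude neither explanation. Tissue composition, these 2 samples, chance among 13796 genes and the kidney status of the animals all stay open, and none of the 24 passed.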

How the results depend on the processing

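The alternatives without HSRA-C replicates 3 and 4 and with the proximal tubule to collecting duct difference as a covariate were chosen after seeing the data. The number of genes past the adjusted threshold was 1, Hoxb5, when the dimmest 50% of genes were left out (adjusted p = 0.0195, where fewer genes are tested), with an intensity trend and robust variance (0.0306), with array weights (0.0252) and at a threshold of 0.1, and it was 0 under each other alternative, where the smallest adjusted p lay between 0.0530 and 0.977. Over all probe sets, where 23371 features are tested, 224 were past p under 0.05 and 1.5-fold. Of these 224, 57 were higher in HSRA-S, against 35 of the 62 genes, so most of them were lower. The 62 genes became 40 without the dimmest 50%, 99 with array weights and 19 without HSRA-C replicates 3 and 4. Leaving out single samples moved them between 21 (without HSRA-C replicate 4) and 132 (without HSRA-C replicate 1 or replicate 2), with 32 without HSRA-C replicate 3 and 40 without HSRA-S replicate 1. The 1663 genes at an unadjusted p under 0.05 became 2573 over all probe sets and 669 without HSRA-C replicates 3 and 4, of which 411 were shared with the 1663. Leaving out single samples gave 1010 (without HSRA-C replicate 3) to 1942 genes, and 1017 without HSRA-C replicate 4. Beyond the number of features or samples, the cause was not tested.

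The number of lists called was 0 with camera's estimated correlation and 0 with fry, and 10 to 16 under the others with the preset correlation. It was 0 with the exact permutation as well, whose smallest possible p of 0.0286 left little room for a call after adjustment. With an estimated correlation it was 0 too without any 1 sample, without HSRA-C replicates 3 and 4 and with the covariate (smallest adjusted p = 0.0998), which was added after seeing the data, so calls gained under these were lost. Single samples decided calls: that of the proximal tubule ended without HSRA-S replicate 4 (shift 0.12), those of glutathione and NRF2 targets (0.080) and chaperones (0.072) without HSRA-S replicate 3, that of chaperones also without HSRA-C replicate 3 (0.065), and that of angiotensin and aldosterone without HSRA-S replicate 4 (-0.020) or HSRA-C replicate 1 (-0.055). Newly called were blood cells without HSRA-C replicate 1 (0.27), cholesterol synthesis without HSRA-C replicate 2 (0.14) or HSRA-S replicate 4 (0.12), smooth muscle without HSRA-S replicate 3 (-0.10), growth factor and mTOR (-0.060) and immediate early genes (-0.081) without HSRA-S replicate 1, adipose genes without any 1 of 5 samples (0.10 to 0.13), and tubular injury (0.12), hypoxia and glycolysis (0.068) and adipose genes (0.098) without HSRA-C replicates 3 and 4. For immediate early genes the sign of the mean changed there, while the test's direction was lower over all 8 samples too. The angiotensin and aldosterone call also ended without the dimmest 50% and with array weights, and that of chaperones after quantile normalization. Also gained were calls of smooth muscle without the dimmest 50% (-0.14), cholesterol synthesis with array weights (0.12), hypoxia and glycolysis over all probe sets (0.053) and with the covariate (0.090), and adipose genes without a filter or after quantile normalization (0.10). With the covariate, 8 of 11 testable called lists kept their call, and matrix (-0.042), fatty acid oxidation (0.088) and angiotensin and aldosterone (-0.013) lost it. The replicate numbers do not pair the samples, since same-numbered samples correlated at -0.068, 0.070, 0.13 and -0.11. With the replicate number as a block, 0 genes passed, 64 were past p 0.05 and 1.5-fold, 1586 were at an unadjusted p under 0.05 and 13 lists were called.

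Sign changes occurred in 4 of 123 named genes and in lists that had not passed. Without HSRA-C replicates 3 and 4, Psca was at 0.11, and the lists were at 0.012 (growth factor and mTOR), -0.027 (interferon), -0.048 (cholesterol synthesis), 0.11 (urothelium), 0.027 (adrenal) and -0.0078 (blood cells). With the covariate, Psca was at 0.41, Upk1b at 0.037, Wee1 at -0.0011, and the lists were at 0.040 (growth factor and mTOR), -0.0016 (clock), 0.22 (urothelium, adjusted p = 0.0318) and 0.0073 (adrenal). The adrenal list was at 0.026 without a filter on dim genes, at 0.0054 over all probe sets and at 0.0044 with the mean over probe sets. Tubular injury was at -0.052 without the dimmest 50% and at -0.0084 with array weights, and the immediate early list at -0.015 and -0.037 there and at -0.0022 after quantile normalization. Over samples left out in turn, Krt14 ranged from -0.0025 to 0.20, tubular injury from -0.027 to 0.072, immediate early genes from -0.081 to 0.050, urothelium from -0.19 to 0.038 and adrenal genes from -0.037 to 0.0022. The cause was not tested. Signal over background limits the dimmest genes, which were left out, and the number of arrays limits the rest.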

Other observations

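The test of clock output genes and the comparison with the medullary contrast were written down before those values were examined; the samples they concern were chosen after the result was seen.

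HSRA-S replicate 4 and HSRA-C replicate 1, samples of opposite groups, resembled each other in ways the groups do not give. Among the 28 pairs of samples, HSRA-C replicates 3 and 4 were apart from the other 6 by over 1 on the log2 scale in 58 probe sets, and HSRA-S replicate 4 with HSRA-C replicate 1 in 8, while the other pairs had 0 or 1. The 8 probe sets are not independent. Among them the unnamed probe sets 10830962 and 10875983 had the same values in every sample, and 10727806 nearly so. These were at 3.36 to 3.72 in HSRA-S replicate 4 and HSRA-C replicate 1 and at 6.25 to 6.61 in the others. A second probe set of the lactate dehydrogenase gene Ldha (10908861) was at log2 9.42 and 9.24 in these 2 samples and between 4.61 and 5.49 in the others, although the brighter probe set of Ldha was between 9.21 and 9.51 in all 8 samples. The nucleoside transporter Slc28a2 was at 7.29 and 7.69 in them and up to 6.27 elsewhere, and Clstn2, Nrip3 and Tmem72 were lower in both than in any other sample. These were also the samples lowest in the medullary markers Slc14a2 (4.44 and 5.99) and Aqp4 (5.22 and 5.45) and highest in the proximal tubule to collecting duct difference (2.59 and 2.11, others up to 2.05). Nrip3 and Tmem72 were highest in HSRA-C replicates 3 and 4, so both genes ran along the same contrast. Slc28a2 was lowest there, at 5.93 and 5.68, but only by a small margin, with HSRA-C replicate 2 at 5.96. No explanation of the Ldha probe set was tested.

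The same 2 samples stood apart in clock genes, although the clock list did not differ between the study's groups. Bmal1 was at 5.58 in HSRA-S replicate 4 and 5.60 in HSRA-C replicate 1 and between 6.16 and 7.19 in the others, Npas2 at 6.22 and 5.79 against 6.88 to 7.71, and Hlf at 5.96 and 6.42 against 5.10 to 5.32. The other samples were not alike. Over HSRA-S replicates 1, 2 and 3 Bmal1 fell from 7.19 to 6.49 and 6.25, and Per3 rose from 6.50 to 6.98 and 7.41. Over HSRA-C replicates 2, 3 and 4 Bmal1 fell from 6.69 to 6.38 and 6.16, and Per3 rose from 7.05 to 7.45 and 7.61. Per1, Per2 and Hlf did not keep such an order in both groups. One hypothesis is that tissue of HSRA-S replicate 4 and HSRA-C replicate 1 was taken at another phase of the day. It needs clock output genes to move against Bmal1: over Per1, Per2, Per3, Dbp and Tef the median difference between these 2 samples and the other 6 was 0.52, with Per3 at 0.77, Dbp at 0.61 and Per1 alone on the other side at -0.38. Tissue composition stays open. Over the clock genes the contrast of these samples and that of HSRA-C replicates 3 and 4, at the other end of the medullary markers, correlated at 0.58 across genes rather than running opposite ways, but it is itself open whether the latter held more medulla, and genes are not independent replicates. The collection time is not given in the sources used here, so this may only be taken as a hypothesis found and tested on the same samples, and since each group holds 1 of the 2 samples it does not separate the groups.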
